A study of Rattus norvegicus with 48 samples.

How the data were processed

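Small RNA was sequenced from 4 nephron segments of the rat kidney, cut out of frozen sections by laser capture: the proximal tubule, the glomerulus, the thick ascending limb of the loop of Henle and the collecting duct. The animals were 3 untreated male Sprague-Dawley rats aged 6 months, and the sections were 8 µm thick. Per the labels' protocols, tubule regions were chosen by antibody fluorescence, against glutathione S-transferase for the proximal tubule, Tamm-Horsfall protein for the thick ascending limb and aquaporin-2 for the collecting duct. Glomeruli were found with a histochemical stain, so the kind of staining differs between glomerulus and tubules in every rat and its effect cannot be separated from the segment. Libraries were made with the TruSeq small RNA kit and read as 50 bp single ends on a HiSeq2000, and every library was run on 4 flow cells, called A to D.

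The table holds 11 libraries, which are 3 each of proximal tubule, thick ascending limb and collecting duct and 2 of glomerulus, giving 44 runs. The glomerulus libraries carry the labels rat 1 and rat 3. A further glomerulus library, also labelled rat 3, was marked by the submitters as left out of their analysis in its 4 runs and is not analysed here. No glomerulus library carries the label rat 2. The rat of each library was taken as labelled.

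The deposited values are a signal that the authors made from read counts by TMM normalization, per the name of their file, with miRNAs of low counts filtered out; 188 mature miRNAs remained. Per the submitters' processing notes the tools were Partek 6.0, Bowtie2 2.2.5 and Bowtie 1.0.0, with the rat genome build rn6. The values were used as deposited. The low values of a run lay mostly on whole multiples of 1 step, taken as the value of 1 read. Between 88.3% and 99.0% of the values up to 30 reads were whole within 0.03 reads, and the others were fractions, so that whole reads were not recovered for all miRNAs and no count test was run. The tolerance and the limit of 30 reads were set after the values had been seen. The steps give an estimate of the reads behind the 188 miRNAs, from 147996 in the glomerulus library of rat 3 to 1296995 in the thick ascending limb library of rat 3. They say nothing of reads outside the table. In simulated runs the step was found within 1% in 44 of 44.

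Values are given as the mean over the 4 runs of a library and then as mean ± SD over the rats. For tests, log2(value + 1) was averaged over the 4 runs, so that n counts rats and not runs. A fold change is on this scale, which understates the change of miRNAs with low values. A miRNA at 0 in every run of a segment has a floor of 3 reads over the group, equal to a value of 0.302 in the proximal tubule, 0.445 in the glomerulus, 0.255 in the thick ascending limb and 0.287 in the collecting duct. Floors cover counting error only, since reads made by PCR are not independent molecules.

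Tests used limma 3.58.1 in R 4.3.3, with a moderated linear model of segment and rat over all 11 libraries and a variance trend with abundance (lmFit and eBayes), and Benjamini-Hochberg adjustment over 188 miRNAs at 0.05. All tests were two-sided. An F-test asked whether a miRNA differed among the 4 segments. Each segment was compared with the mean of the other segments and with each other segment. A peak in 1 of the other segments raises their mean, and can by itself make a segment lower against it. A trough in 1 of them lowers the mean, and can likewise make a segment higher. A miRNA was called enriched in a segment when it was higher than in each of the other segments at an adjusted p below 0.05. The model leaves 5 residual degrees of freedom per miRNA and estimated no differences in variance beyond the trend, so miRNAs of like abundance share 1 variance and a noisy miRNA can pass more easily than its own spread would allow. The very small adjusted p given below rest on this shared variance. The trend was estimated from all segments, while the glomerulus libraries spread more: the median SD of log2 values between rats was 0.811 in the glomerulus, against 0.284 in the proximal tubule, 0.343 in the thick ascending limb and 0.344 in the collecting duct, over 65 miRNAs with a mean of at least 100.

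The rat enters as a replicate block because segments of 1 rat come from the same animal. In the values the pairing was weak: deviations from the segment means had a median correlation of 0.03 over 15 pairs of libraries of the same rat, 11 of them above 0, against −0.01 over 30 pairs from different rats. The deviations of a segment sum to 0 by construction, which ties these values together, so the second is no separate reference. The fit with the rat as a random effect estimated a correlation of −0.158 between libraries of 1 rat.

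Before the data were examined, 21 lists of miRNAs were fixed. They hold the miR-192/miR-194/miR-215, miR-204/miR-211, miR-200, miR-183/miR-96/miR-182, miR-30, miR-10/miR-196, miR-143/miR-145, miR-199/miR-214, let-7/98, miR-17/92, Dlk1-Dio3, miR-322/miR-503, miR-34/miR-449 and miR-23/miR-27/miR-24 families or clusters, endothelial, erythroid, leukocyte, striated muscle, neuronal and hepatocyte markers, and miRNAs reported to respond to kidney injury. The 11 lists with at least 3 measured members were tested in each segment against the others with camera from limma at a preset correlation of 0.01, adjusted over 44 tests. Camera sets a list against the other miRNAs, so higher or lower by camera is relative to them and not to 0. Tests with an estimated correlation and with fry were alternatives. The rule for named miRNAs was fixed at the same time: in each segment against the others, the 12 largest increases and 8 largest decreases past the threshold with the same sign in every rat; up to 4 members of highest mean per list; the 5 most abundant per segment; the 3 largest in each direction per pair of segments; and every member of a count of 5 or fewer. The miRNAs given in passing outside this rule were singled out after their values were seen.

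Pairs of miRNAs with identical values in every run count as separate entries among the 188: let-7a-5p with miR-3596a, miR-181a-1-3p with miR-3570, miR-210-3p with miR-3574, and miR-3557-3p with miR-378a-5p. Values of miRNAs whose hairpins overlap, such as miR-203a-3p with miR-203b-3p or miR-3553 with the miR-183 gene, are uncertain because the counting could split or double their reads. Gene names and neighbours came from a RefSeq table of the assembly GRCr8, which differs from rn6, so no coordinates are given; 170 miRNAs matched 1 gene, 18 matched several and 0 matched none.

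The procedure was tested on simulated data, with 45 of 188 miRNAs changed in 20 sets. At true folds of 2, 4 and 8 the test found 16.3%, 61.0% and 88.3% of changed miRNAs in the proximal tubule, 9.00%, 45.0% and 71.0% in the glomerulus, 20.0%, 56.3% and 86.0% in the thick ascending limb and 18.7%, 61.0% and 89.0% in the collecting duct. False calls made up 4.05%, 3.85%, 2.79% and 3.62% of calls in these segments. A list shifted in the collecting duct was found in 20 of 20 sets, and 2.27% of unshifted lists had an unadjusted p below 0.05. The simulated members of a list varied independently, so these shares do not cover lists whose members vary together. The simulation gave all segments the same spread, and so does not cover the wider spread of the glomerulus libraries. It also drew the noise of each miRNA with the variance that the test assumes. The share of false calls therefore does not cover miRNAs noisier than others of like abundance.

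Alternatives covered the rat as a random effect or left out, pseudocounts of 0.5 and 10, filters on low values, rescaling of the values by median of ratios, to the same total or by quantiles, other variance models, each flow cell alone, and each library or rat left out. Counting identical miRNAs once, leaving out flow cell D and fitting the tubule segments alone were added after the data had been seen.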

Results

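The series profiles the miRNAs of 4 nephron segments in healthy rats, so that a miRNA in urine might be traced to the part of the nephron it came from. Values are given for 188 mature miRNAs in 3 libraries each of proximal tubule, thick ascending limb and collecting duct and in 2 glomerulus libraries, from 3 rats. The steps between low values put the reads behind the 188 miRNAs at 544752, 914255 and 241314 in the proximal tubule libraries of rats 1, 2 and 3. The glomerulus libraries held 807909 reads in rat 1 and 147996 in rat 3. The thick ascending limb libraries held 218882, 321577 and 1296995, and the collecting duct libraries 744044, 788819 and 631114. The summed value of a library ranged from 77457 in the glomerulus of rat 3 to 255518 in the collecting duct of rat 2. In the glomerulus 51 miRNAs were at 0 in all runs of rat 3 and 30 in all runs of rat 1. Runs of the same library on the 4 flow cells differed little, with a median SD of 0.12 on the log2 scale, against 0.38 between rats, over 65 miRNAs with a mean of at least 100.

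miR-10a-5p, which lies in a Hox gene cluster, was the most abundant miRNA of every segment. It took 25.1% ± 1.97 of the summed values in the proximal tubule (SD, n = 3), 20.4% ± 3.27 in the glomerulus (n = 2), 49.2% ± 0.687 in the thick ascending limb (n = 3) and 47.0% ± 3.39 in the collecting duct (n = 3). miR-22-3p ranked next in every segment, at 14.4% ± 1.63, 13.8% ± 0.920, 6.88% ± 0.894 and 8.57% ± 1.01 in the same order. The next place went to miR-192-5p in the proximal tubule, at 13.0% ± 2.73. It went to miR-143-3p, known from smooth muscle and mesangial cells, in the glomerulus and the thick ascending limb, at 11.6% ± 2.43 and 3.88% ± 0.303. In the collecting duct it went to miR-182, at 4.23% ± 1.76. The 5 most abundant miRNAs together held 62.8%, 61.5%, 67.6% and 68.6%. Across miRNAs, which are not independent replicates, the profiles of thick ascending limb and collecting duct were the closest of the segment pairs, with a median Spearman rho of 0.913, and those of glomerulus and collecting duct the least alike, at 0.789. Libraries of 1 segment had medians from 0.878 to 0.930.

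By the limma F-test with Benjamini-Hochberg adjustment, 46 of 188 miRNAs differed among the 4 segments. Enriched miRNAs, higher in 1 segment than in each of the others, numbered 4 in the proximal tubule (miR-192-5p, miR-194-5p, miR-411-5p and miR-541-5p), 3 in the glomerulus (miR-23b-3p, miR-351-5p and miR-450a-5p) and 3 in the collecting duct (miR-31a-5p, miR-182 and miR-205). In the thick ascending limb limma found 0, although 2 miRNAs were higher there than in the other segments combined and 25 differed either way at an unadjusted p below 0.05. The F-test count became 85 without the glomerulus library of rat 1 and 70 without that of rat 3. The proximal tubule number became 14 without the rat 1 glomerulus library. The glomerulus number became 1 without the rat 1 glomerulus, rat 2 proximal tubule or rat 1 collecting duct library and 5 without the rat 3 glomerulus library. The thick ascending limb number became 1 without the rat 1 glomerulus library. The collecting duct number became 12 without the rat 1 glomerulus library, 7 without the rat 3 glomerulus library, 0 without the rat 2 collecting duct library, and 1 without the rat 2 proximal tubule library, any thick ascending limb library or either other collecting duct library.

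**Figure D1:**
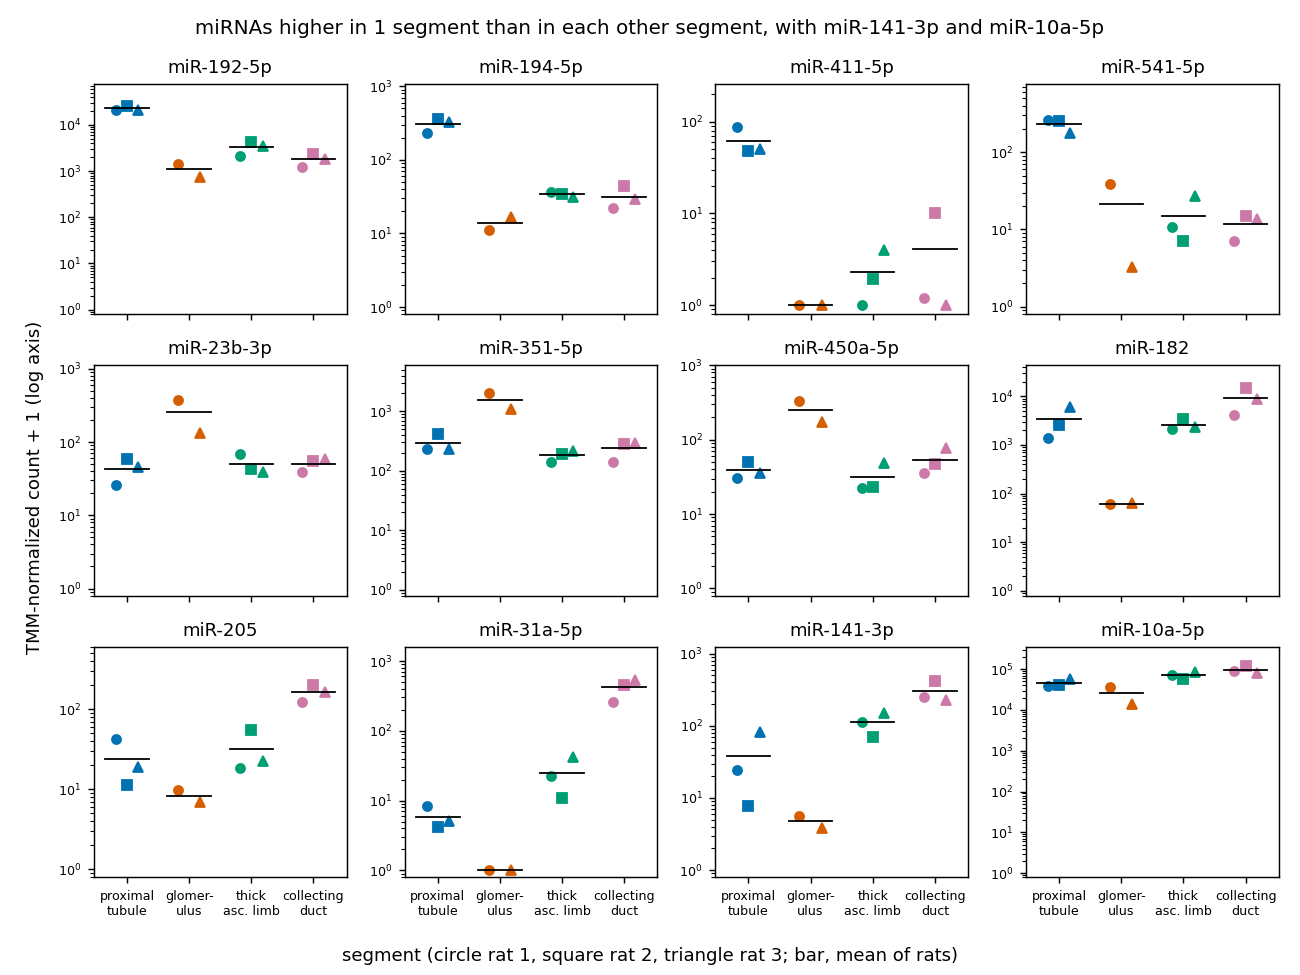
Value + 1 on a log axis (TMM-normalized, mean over 4 runs of a library) of 12 miRNAs in the 4 segments; each point is the library of 1 rat and each bar the segment mean. miR-192-5p stands at 22626 in the proximal tubule against 1088 to 3265 elsewhere, and miR-31a-5p at 417 in the collecting duct against 0 in the glomerulus.

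The proximal tubule, which reabsorbs most of the filtrate, stood out by miR-192-5p and miR-194-5p, miRNAs of shared clusters known to be abundant in kidney epithelium. miR-192-5p had a mean value of 22626 ± 2930 (SD, n = 3) there, 12.1-fold above the other segments (log2 3.60 ± 0.38, SE), and miR-194-5p one of 306 ± 65.5, 12.6-fold above them (log2 3.66 ± 0.56). miR-411-5p and miR-541-5p, from the imprinted Dlk1-Dio3 cluster, had means of 60.6 ± 21.7 and 229 ± 44.2, and were higher by 5.08 ± 0.89 and 4.45 ± 0.66 on the log2 scale. miR-411-5p was at 0 in every glomerulus run, which puts the proximal tubule at least 136-fold higher than the glomerulus. miR-203a-3p, known from skin, was higher by 3.26 ± 0.77 and miR-375-3p, known from pancreatic islets, by 2.45 ± 0.43.

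All of these were higher in 3 of 3 rats. In limma with Benjamini-Hochberg adjustment their adjusted p ran from 4.2e-18 for miR-192-5p to 0.00064 for miR-203a-3p. Over the alternative settings other than single libraries or rats left out, it reached 0.00096 for miR-192-5p and 0.025 for miR-203a-3p. The log2 value of miR-411-5p was 4.41 without the proximal tubule library of rat 1, and that of miR-541-5p 5.25 and 3.66 without the glomerulus libraries of rats 1 and 3. Against the other tubule segments alone miR-375-3p was at 1.09, miR-203a-3p at 2.08 and miR-203b-3p at 2.96. The test called 24 miRNAs, 21 higher and 3 lower. miR-203b-3p, whose hairpin overlaps that of miR-203a-3p, was higher by 3.69 ± 0.86. miR-409b was higher by 3.63 ± 0.88, a call lost without the proximal tubule library of rat 3 (adjusted p = 0.07). miR-21-5p, known from kidney injury and fibrosis, had a mean of 1230 ± 70.2 and was 2.95-fold higher (adjusted p = 0.0016), a call lost without the proximal tubule library of rat 3 (adjusted p = 0.071). The calls of miR-1249 and miR-342-3p, higher by 3.26 and 2.92, were each lost without the proximal tubule library of rat 2 or rat 3 (adjusted p up to 0.23 and 0.28), and miR-1249 moved to 2.44 without that of rat 2 and 3.96 without that of rat 1. miR-92b-3p was lower by −1.56 ± 0.46, a call lost without any 1 of the proximal tubule libraries (adjusted p up to 0.17). The other lower calls, miR-31a-5p at −1.97 ± 0.71 and miR-27a-3p at −1.29 ± 0.46, were each lost without any 1 proximal tubule or collecting duct library or the thick ascending limb library of rat 1 or rat 3 (adjusted p up to 0.38 and 0.36). The miR-31a-5p value is against a mean that holds its collecting duct peak. Its proximal tubule mean of 4.80 was at least 10.8-fold above the glomerulus. Without a variance trend limma lost miR-21-5p, miR-92b-3p and miR-27a-3p (adjusted p up to 0.064, 0.06 and 0.18), the last also with flow cell D alone. A pseudocount of 0.5 or flow cell A or D alone ended miR-31a-5p (adjusted p up to 0.26).

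Of the lists fixed before the data were examined, both measured members of miR-192/miR-194/miR-215 rose in the proximal tubule. Of 4 Dlk1-Dio3 members 2 rose, and 3 when adjusted over the list alone, while miR-300-3p and miR-127-3p had log2 values of 2.29 and 1.00 at adjusted p of 0.091 and 0.41. The list as a whole was higher by camera (adjusted p = 0.0047), and had an adjusted p = 0.676 with an estimated correlation. The miR-23/miR-27/miR-24 list was lower by camera (adjusted p = 0.0065), with 1 of 7 members lower, 2 when adjusted over the list alone, and an adjusted p = 0.877 with an estimated correlation. The endothelial list was lower by camera (adjusted p = 0.0457) with 0 of 3 members past the limma threshold, 2 when adjusted over the list alone, and an adjusted p = 0.877 with an estimated correlation; 2 of the 3 were at an unadjusted p below 0.05. miR-204-5p, the measured member of miR-204/miR-211 and abundant in kidney epithelium, had a log2 value of 0.83 and did not pass. Of miR-183/miR-96/miR-182, 1 of 2 members rose, miR-182 by 1.31 ± 0.38; without the proximal tubule library of rat 3 it was at 0.67 with an adjusted p = 0.52, without a variance trend its call was lost, and against the tubule segments alone it was lower, at −0.70.

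The median log2 value of all 188 miRNAs in the proximal tubule was 0.36, and rescaling moved it to 0.07 by median of ratios, 0.22 by same total and −0.03 by quantiles. The split of 21 higher and 3 lower became 26 and 23, 31 and 15, and 22 and 25 in that order. The count of 24 became 62 and 37 without the glomerulus libraries of rats 1 and 3, and 13 and 9 without the proximal tubule libraries of rats 2 and 3. In a fit of the tubule segments alone, chosen after the data had been seen, it was 42.

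In the glomerulus, the capillary tuft that filters the blood, the miR-200 family, which keeps cells in an epithelial state by repressing ZEB transcription factors, fell in 4 of 5 members: miR-141-3p by 24.5-fold (log2 −4.61 ± 0.66, SE), miR-200a-3p by 18.2-fold (−4.19 ± 0.64), miR-429 by 10.1-fold (−3.34 ± 0.57) and miR-200b-3p by 9.47-fold (−3.24 ± 0.52), against the other segments. miR-182 had a mean of 60.8 ± 2.58 (SD, n = 2) against 2591 to 9194 in the tubule segments, 55.3-fold lower. miR-375-3p was 21.6-fold lower, at 18.9 ± 4.35. Higher in the glomerulus were miR-351-5p, at 1558 ± 624 and 7.47-fold, miR-126a-5p, an endothelial miRNA, at 4723 ± 1027 and 2.97-fold, and miR-149-5p, at 111 ± 53.3 and 11.1-fold.

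In limma with Benjamini-Hochberg adjustment 37 miRNAs passed, 9 higher and 28 lower, with 2 glomerulus libraries. Adjusted p were 2.5e-32 for miR-182, 1e-15 for miR-375-3p, 2e-10 for miR-141-3p, 1.4e-07 for miR-351-5p, 0.0034 for miR-149-5p and 0.0054 for miR-126a-5p, each with the same sign in 2 of 2 rats. Over the alternative settings other than single libraries or rats left out, the first 4 calls held. Their limma adjusted p there reached 0.00034 for miR-182, 0.00075 for miR-375-3p, 0.0029 for miR-141-3p and 0.0076 for miR-351-5p. The call of miR-200a-3p (adjusted p = 3e-09) was lost without the glomerulus library of rat 3 (adjusted p = 0.064), where its change was −1.60, against −6.78 without that of rat 1. miR-3553, which lies at the miR-183 gene, was lower by −5.89 ± 0.60, miR-672-5p by −4.78 ± 0.61 and miR-203a-3p by −4.24 ± 0.92. The glomerulus libraries differed widely, and without that of rat 1 or rat 3 the log2 values were −7.87 and −3.90 for miR-3553, −7.07 and −2.50 for miR-672-5p, −5.17 and −3.31 for miR-203a-3p, −5.24 and −3.98 for miR-141-3p, −4.28 and −2.21 for miR-200b-3p, and 2.19 and 3.61 for miR-351-5p. In the same order they were 1.74 and 3.54 for miR-450a-5p, 1.52 and 3.21 for miR-23b-3p, 0.70 and 2.30 for miR-126a-3p, and −2.39 and −0.74 for miR-10a-5p. miR-31a-5p was at 0 in every glomerulus run, at least 937-fold below the collecting duct. miR-450a-5p and miR-23b-3p, higher by 2.64 ± 0.66 and 2.37 ± 0.64, lost their calls without the glomerulus library of rat 1 (adjusted p = 0.052 and 0.078). miR-138-5p, higher by 3.42 ± 1.08 and at 0 in every collecting duct run, lost its call without either glomerulus library (adjusted p up to 0.15). miR-126a-3p, 2.83-fold higher, lost its call without the rat 1 or rat 2 proximal tubule, rat 1 glomerulus, rat 1 thick ascending limb, or rat 1 or rat 3 collecting duct library (adjusted p up to 0.26). miR-10a-5p was lower by −1.57 ± 0.51, a call lost without the rat 3 library of the proximal tubule, glomerulus or thick ascending limb (adjusted p up to 0.35). Array weights, 0.248 for each glomerulus library, ended the calls of miR-149-5p, miR-138-5p, miR-126a-3p, miR-126a-5p, miR-23b-3p, miR-203a-3p and miR-450a-5p (adjusted p up to 0.28, 0.45, 0.40, 0.16, 0.16, 0.096 and 0.092) and of miR-10a-5p. The calls of miR-126a-5p, miR-126a-3p and miR-10a-5p were lost without a variance trend, those of miR-138-5p and miR-126a-3p with flow cell D alone, and that of miR-126a-3p with flow cell A alone. Quantile normalization gives miR-10a-5p, the highest miRNA of every library, the same value everywhere by construction and so ended its call.

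The miR-200 list was lower by camera (adjusted p = 0.00061), with 4 members also when adjusted over the list alone and an adjusted p = 0.676 with an estimated correlation. The miR-322/miR-503 list, an X-linked cluster, was higher by camera (adjusted p = 0.0065) with 2 of 3 members higher, miR-351-5p and miR-450a-5p, 2 when adjusted over the list alone, and an adjusted p = 0.779 with an estimated correlation. The miR-23/miR-27/miR-24 list was higher by camera (adjusted p = 0.0266), with 1 of 7 members past the threshold, 3 when adjusted over the list alone, and an adjusted p = 0.877 with an estimated correlation. Of 3 endothelial members 2 were higher, miR-126a-5p and miR-126a-3p, and 2 when adjusted over the list alone; the list had a camera adjusted p = 0.239. miR-143-3p and miR-145-5p, markers of smooth muscle, pericytes and mesangial cells, had log2 values of 0.95 and 1.61 with adjusted p = 0.13 for each, and passed when adjusted over the list alone. Both miR-192/miR-194/miR-215 members fell, miR-192-5p by 4.25-fold and miR-194-5p by 4.63-fold (adjusted p = 7e-05 and 0.0092). These folds are against a mean that holds the proximal tubule, where both are enriched. They say little of the difference from the thick ascending limb or collecting duct. The call of miR-194-5p was lost with array weights or flow cell D alone (adjusted p up to 0.26), and miR-192-5p was at −2.74 and −1.44 without the glomerulus libraries of rats 1 and 3. miR-199a-3p, of the mesenchymal miR-199/miR-214 list, was lower by −2.69 ± 0.63, 1 of 2 members; the call was lost without the glomerulus library of rat 3 (adjusted p = 0.15) and with array weights (adjusted p = 0.05), and the value was −3.98 and −1.39 without the glomerulus libraries of rats 1 and 3.

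The median log2 value of all miRNAs in the glomerulus was −0.56 and moved under rescaling to −0.20 by median of ratios, −0.08 by same total and 0.02 by quantiles. The split of 9 higher and 28 lower became 25 and 31, 31 and 28, and 25 and 21, so lower miRNAs were still in excess by median of ratios and no longer by same total or quantiles. Without the glomerulus library of rat 1, 3 were higher and 69 lower, and without that of rat 3, 11 and 15.

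The thick ascending limb, the diluting segment of the nephron, differed from the others in 4 miRNAs. miR-375-3p was 4.02-fold higher (log2 2.01 ± 0.43, SE) at a mean of 589 ± 130 (SD, n = 3), and miR-141-3p of the miR-200 family 3.53-fold higher (1.82 ± 0.55) at 111 ± 40.1. let-7d-3p was 3.36-fold lower (−1.75 ± 0.43) at 101 ± 53.3, and miR-351-5p 2.66-fold lower (−1.41 ± 0.42). Each had its sign in 3 of 3 rats, with adjusted p of 0.00059, 0.0497, 0.006 and 0.046 by limma with Benjamini-Hochberg adjustment. The mean of miR-375-3p in the proximal tubule, 825 ± 521, was above that in the thick ascending limb, and miR-141-3p was at 300 ± 103 in the collecting duct.

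The miR-200 list was higher in the thick ascending limb by camera (adjusted p = 0.0046) with 1 of 5 members past the threshold, 1 when adjusted over the list alone, and an adjusted p = 0.779 with an estimated correlation. This is against a mean that holds the glomerulus, where the median log2 value of the list was −3.34. The list median was 0.87 in the thick ascending limb, 0.59 in the proximal tubule and 1.89 in the collecting duct. The call of miR-375-3p was lost without the thick ascending limb library of rat 1 or rat 2 (adjusted p up to 0.078), and that of let-7d-3p without either of these or the rat 2 library of the proximal tubule or collecting duct (adjusted p up to 0.47). The calls of miR-141-3p and miR-351-5p were lost without the rat 1 or rat 2 proximal tubule, any thick ascending limb, or the rat 1 or rat 3 collecting duct library, and that of miR-351-5p also without the rat 2 collecting duct library (adjusted p up to 0.86 for each). Without a variance trend all 4 calls were lost, with adjusted p = 0.17 for miR-375-3p and up to 0.31 for let-7d-3p, which flow cell D alone ended as well. Against the other tubule segments alone miR-375-3p was at 0.60 and miR-141-3p at 0.32, neither past the threshold. The call of miR-141-3p held in 8 of 19 alternative settings (log2 up to 2.12, adjusted p up to 0.67). It was also lost without the rat as block or with it as a random effect, with a pseudocount of 0.5 or 10, by quantile normalization, with flow cell B, C or D alone and without flow cell D. That of miR-351-5p was also lost with the rat as a random effect, flow cell A or D alone, or tubule segments only (adjusted p up to 0.32). The count of 4 became 16 and 34 without the glomerulus libraries of rats 1 and 3, 0 without the thick ascending limb library of rat 1 or rat 2, 1 without the rat 2 proximal tubule library, and 2 without the rat 1 proximal tubule, rat 3 thick ascending limb or any 1 collecting duct library. Rescaling moved the median of all miRNAs from −0.16 to 0.07 by median of ratios, −0.01 by same total and 0.04 by quantiles, and the split of 2 higher and 2 lower to 11 and 8, 11 and 14, and 3 and 4.

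The collecting duct, the last segment, was marked by miR-31a-5p, miR-182 and miR-205, all known from epithelia. miR-141-3p, also known from epithelia, was higher against the mean of the other segments but was not among the enriched miRNAs. Its difference from the thick ascending limb did not pass. miR-31a-5p had a mean of 417 ± 144 (SD, n = 3) against 24.2 ± 16.0 in the thick ascending limb and 4.80 ± 2.15 in the proximal tubule (log2 6.46 ± 0.71 against the other segments, SE). miR-182 reached 9194 ± 5204, 10.3-fold above the others, miR-205 161 ± 39.3, 9.58-fold, and miR-141-3p 300 ± 103, 13.5-fold. miR-9a-5p, known from neurons, stood at 58.9 ± 9.64, 21.4-fold higher, and miR-92b-3p was higher by 2.74 ± 0.46.

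The limma adjusted p with Benjamini-Hochberg adjustment were 6e-17 for miR-31a-5p, 4.1e-16 for miR-182, 1.3e-09 for miR-141-3p, 1.4e-07 for miR-92b-3p, 4.7e-06 for miR-205 and 5.7e-06 for miR-9a-5p, each higher in 3 of 3 rats. Over the alternative settings other than single libraries or rats left out, these calls held. Their adjusted p there reached 4e-05, 0.0033, 0.005, 0.0044, 0.023 and 0.00098 in the same order. Without the collecting duct library of rat 2 miR-141-3p was at 3.02. Against the other tubule segments alone miR-31a-5p was at 5.28, miR-141-3p at 2.50, miR-182 at 1.61, miR-429 at 0.87, miR-200b-3p at 0.81 and miR-192-5p at −2.27. The test called 23 miRNAs, 20 higher and 3 lower. Of the miR-200 list 4 of 5 members rose, and 4 when adjusted over the list alone; the list was higher by camera (adjusted p = 0.00062), with an adjusted p = 0.676 with an estimated correlation. Besides miR-141-3p these were miR-200a-3p (2.06 ± 0.54), miR-429 (1.89 ± 0.48) and miR-200b-3p (1.80 ± 0.44), whose calls were lost without the collecting duct library of rat 2 (adjusted p up to 0.13, 0.14 and 0.10) and, for miR-200a-3p, also without that of rat 3. miR-200a-3p was at 2.93 and 1.20 without the glomerulus libraries of rats 1 and 3. The call of miR-200b-3p was also lost without a variance trend (adjusted p = 0.078). That of miR-200a-3p was also lost there, with the rat as a random effect, by same total or quantiles, with flow cell D alone and with tubule segments only (adjusted p up to 0.19). Both miR-183/miR-96/miR-182 members rose, miR-96-5p by 2.85 ± 0.88, a call lost without the rat 2 thick ascending limb or the rat 1 or rat 3 collecting duct library (at 2.13 without the last, adjusted p up to 0.28), with the rat as a random effect or with flow cell D alone. miR-10a-5p was higher by 1.24 ± 0.42, lost without the rat 1 or rat 2 proximal tubule or thick ascending limb library or any 1 collecting duct library (adjusted p up to 0.30), without a variance trend, with flow cell B or D alone, with tubule segments only, and by quantile normalization, which leaves it no change by construction. miR-192-5p was lower by −1.33 ± 0.38, a call lost without any 1 collecting duct library (adjusted p up to 0.18) or without a variance trend (adjusted p = 0.13). miR-138-5p was lower by −2.89 ± 0.90 and was at 0 in every run here, at least 122-fold below the glomerulus. The call was lost without the rat 2 proximal tubule or the rat 1 or rat 3 collecting duct library, with flow cell B or D alone, or with tubule segments only (adjusted p up to 0.15).

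The count of 23 in the collecting duct became 38 without the rat 1 glomerulus library, 15 without the rat 2 thick ascending limb library, and 13, 11 and 10 without the collecting duct libraries of rats 1, 2 and 3. Rescaling moved the median of all miRNAs from 0.23 to −0.08 by median of ratios, −0.24 by same total and −0.10 by quantiles. The split of 20 higher and 3 lower became 22 and 10, 19 and 18, and 17 and 10.

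**Figure D2:**
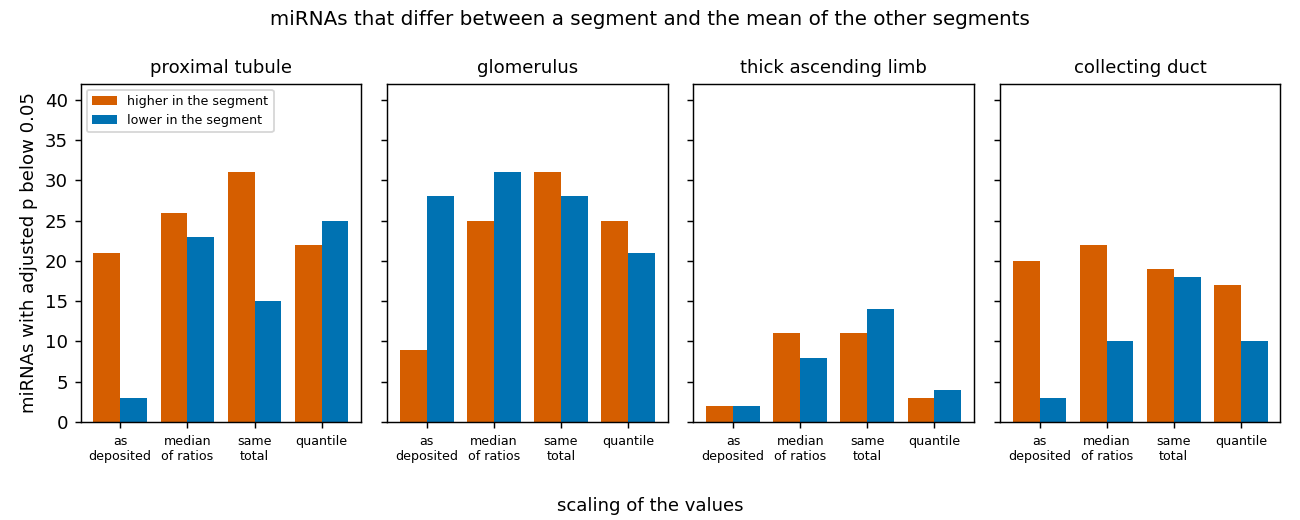
Numbers of miRNAs higher and lower in each segment against the others (vertical axis, miRNAs with an adjusted p below 0.05) for the deposited values and 3 rescalings. In the glomerulus the deposited values give 9 higher and 28 lower, and quantile normalization 25 and 21.

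Pair by pair, the proximal tubule differed from the glomerulus in 33 miRNAs, 26 higher and 7 lower. miR-3553 was higher by 5.82 ± 0.69 (log2, SE; n = 3 and 2) and miR-203a-3p by 5.62 ± 1.06, while miR-351-5p was lower by −2.57 ± 0.57, at adjusted p of 6.5e-15, 3.3e-06 and 0.00012 in limma with Benjamini-Hochberg adjustment. Without the glomerulus libraries of rats 1 and 3 these were 7.80 and 3.83, 6.55 and 4.70, and −1.86 and −3.28, and miR-3553 was at 4.93 without the rat 3 proximal tubule library. From the thick ascending limb it differed in 15, 13 higher and 2 lower, led by miR-411-5p at 4.98 ± 1.07 and miR-541-5p at 4.35 ± 0.79 (adjusted p = 0.00016 and 3.9e-06). Without the rat 3 thick ascending limb library these were 5.78 and 5.37, and miR-411-5p was at 4.35 and 5.64 without the proximal tubule libraries of rats 1 and 2. The lower ones were miR-141-3p at −2.09 ± 0.66 (adjusted p = 0.03), lost without the rat 1 or rat 2 proximal tubule, any thick ascending limb, or the rat 1 or rat 2 collecting duct library (adjusted p up to 0.51) and at −1.27 and −2.95 without the proximal tubule libraries of rats 2 and 3, and miR-92b-3p at −1.94 ± 0.55 (adjusted p = 0.011), lost without the rat 1 or rat 2 library of either segment (adjusted p up to 0.26). Both were also lost without a variance trend or with flow cell D alone, and miR-141-3p with the rat as a random effect or flow cell B alone (adjusted p up to 0.18, and 0.081 for miR-92b-3p). From the collecting duct it differed in 19, 11 higher and 8 lower, with miR-192-5p at 3.69 ± 0.45 and miR-31a-5p at −6.33 ± 0.84 (adjusted p = 2.2e-13 and 1.2e-11).

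The proximal tubule and glomerulus count of 33 became 73 without the rat 1 glomerulus library and 20 without the rat 3 proximal tubule library. Against the thick ascending limb the 15 became 37 and 36 without the glomerulus libraries of rats 1 and 3, 8, 5 and 9 without the proximal tubule libraries of rats 1, 2 and 3, 5, 5 and 9 without the thick ascending limb libraries, and 9 without the rat 1 or rat 2 collecting duct library. Against the collecting duct the 19 became 40 and 39 without the glomerulus libraries and 12 and 10 without the proximal tubule libraries of rats 1 and 2. Under median of ratios, same total and quantiles the splits of higher and lower miRNAs were 29 and 22, 29 and 21, and 22 and 20 against the glomerulus, and 14 and 8, 15 and 7, and 11 and 12 against the thick ascending limb. Against the collecting duct they were 19 and 22, 25 and 13, and 19 and 19. The median of all miRNAs in these pairs was 0.77, 0.37 and 0.16 with the deposited values, and 0.24, −0.08 and 0.14 by median of ratios, 0.24, 0.07 and 0.37 by same total, and 0.00, −0.07 and 0.00 by quantiles.

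The glomerulus differed from the thick ascending limb in 21 miRNAs, 6 higher and 15 lower. miR-149-5p was higher by 4.24 ± 1.11 and miR-351-5p by 3.24 ± 0.57 (log2, SE; n = 2 and 3), and miR-182 was lower by −5.18 ± 0.52 and miR-375-3p by −4.83 ± 0.59, at adjusted p of 0.0019, 7.2e-07, 8.5e-20 and 7.5e-14 by limma with Benjamini-Hochberg adjustment. From the collecting duct it differed in 28, 7 higher and 21 lower. There miR-149-5p was higher by 3.95 ± 1.11 (adjusted p = 0.004), and miR-182 was lower by −6.86 ± 0.52 (adjusted p = 5.8e-34) and miR-3553 by −6.50 ± 0.69 (adjusted p = 2.3e-18). With array weights miR-149-5p lost both calls (adjusted p = 0.13 and 0.17). Without the glomerulus libraries of rats 1 and 3 miR-351-5p was at 2.52 and 3.95 against the thick ascending limb, and miR-3553 at −8.49 and −4.52 against the collecting duct. The 21 became 44 and 36 without the glomerulus libraries of rats 1 and 3, and the 28 became 67 without that of rat 1. The splits under median of ratios, same total and quantiles were 21 and 24, 22 and 21, and 17 and 17 against the thick ascending limb, and 22 and 22, 31 and 19, and 24 and 19 against the collecting duct. The medians of all miRNAs were −0.36 and −0.61 as deposited, −0.24 and −0.07 by median of ratios, −0.13 and 0.11 by same total, and −0.01 and 0.05 by quantiles.

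The thick ascending limb and collecting duct, both downstream of the proximal tubule, differed in 4 miRNAs in the main fit, all lower in the thick ascending limb. That fit shares its variance with the glomerulus libraries, which spread more between rats. With tubule segments only the count was 26, 5 higher and 21 lower in the thick ascending limb, so the 4 do not show that the segments are alike. miR-31a-5p was lower by −4.22 ± 0.84 (log2, SE; n = 3 and 3), miR-205 by −2.52 ± 0.74, miR-423-5p by −1.69 ± 0.45 and miR-182 by −1.68 ± 0.45, with limma and Benjamini-Hochberg adjusted p of 0.00011, 0.032, 0.014 and 0.014. The model without the rat as replicate block gave 7 in place of 4. The miR-31a-5p call was lost without the collecting duct library of rat 2 (adjusted p = 0.079). The calls of miR-205, miR-423-5p and miR-182 were lost without the rat 2 proximal tubule, any thick ascending limb, or the rat 2 or rat 3 collecting duct library, and those of miR-205 and miR-182 also without the rat 1 collecting duct library (adjusted p up to 0.50, 0.43 and 0.38), with miR-205 at −3.12 without the rat 2 thick ascending limb library and miR-423-5p at −2.27 without the rat 1 collecting duct library. These 3 calls were also lost with the rat as a random effect, by same total or quantiles, without a variance trend and with flow cell D alone (adjusted p up to 0.26, 0.39 and 0.35). That of miR-205 ended with a pseudocount of 0.5, by median of ratios and with flow cell B or C alone as well. The count became 26 without either glomerulus library, 0 without the rat 2 collecting duct library, 2 without that of rat 1, and 1 without the rat 2 proximal tubule, any 1 thick ascending limb or the rat 3 collecting duct library. The split of 0 higher and 4 lower became 4 and 5 by median of ratios, 4 and 1 by same total and 4 and 2 by quantiles, while the median of all miRNAs went from −0.36 to 0.07, 0.15 and 0.10.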

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

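Added after the data had been seen were the fits with identical miRNAs counted once, without flow cell D and with tubule segments only; the other settings were chosen before. The planned count tests were not run, since whole reads were not recovered, nor was the removed glomerulus library put back, which is not analysed here. Of 290 values for named miRNAs, 99 passed the threshold, and 52 of these passed with each of the 11 libraries left out in turn. Their fold moved by over 1.5 times in 29 of the 99 without either glomerulus library, 34 and 32 without rats 1 and 3, 52 with a pseudocount of 10, which shrinks low values by construction, 39 by quantile normalization, 19 by same total, 15 with a pseudocount of 0.5 and 22 of 56 with tubule segments only; under each other setting it did so in at most 8. Few reads limit the glomerulus of rat 3, with 147996 for the 188 miRNAs and as few as 15771 in a run. Where a count moved, the cause was not tested, except where fewer miRNAs or libraries entered by construction. Counts are of miRNAs with an adjusted p below 0.05 (limma, Benjamini-Hochberg).

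Without the rat as replicate block, thick ascending limb against collecting duct gave 7 in place of 4, and no other count moved by over 1.5 times. Of the named values 278 of 290 kept their side of the threshold. With the replicate block as a random effect the thick ascending limb gave 2, proximal tubule against collecting duct 11, thick ascending limb against collecting duct 1, and 1 miRNA was enriched in the collecting duct. A pseudocount of 10 gave 7 enriched in the proximal tubule and 7 in the glomerulus. Only miRNAs with a mean at or above the median, 94 of them, gave 12 for proximal tubule against collecting duct and 5 lists in place of 8. A mean of at least 100, which left 65 miRNAs, gave 26 among the segments, 22 in the glomerulus, 21 for proximal tubule against glomerulus, 10 for proximal tubule against collecting duct, 14 for glomerulus against collecting duct, 2 enriched in the proximal tubule, 1 in the glomerulus, and 4 lists.

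Median-of-ratios rescaling gave 49 in the proximal tubule, 56 in the glomerulus and 19 in the thick ascending limb. By pair it gave 51 for proximal tubule against glomerulus, 41 for proximal tubule against collecting duct, 45 and 44 for glomerulus against thick ascending limb and collecting duct, 9 for thick ascending limb against collecting duct, and 13 enriched in the glomerulus. Rescaling to the same total gave 70 among the segments, 46 in the proximal tubule, 59 in the glomerulus, 25 in the thick ascending limb and 37 in the collecting duct. By pair it gave 50, 38, 43 and 50 for proximal tubule against glomerulus and collecting duct and glomerulus against thick ascending limb and collecting duct, with 14 enriched in the glomerulus and 1 in the collecting duct. Quantile normalization gave 47 in the proximal tubule, 7 in the thick ascending limb, 23 and 38 for proximal tubule against thick ascending limb and collecting duct, 34 and 43 for glomerulus against the same segments, and 10 enriched in the glomerulus. In the glomerulus miR-26a-5p went from −0.03 to 0.47 by median of ratios and 0.59 by same total, and miR-22-3p from −0.11 to 0.50 by same total.

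Without a variance trend limma gave 0 in the thick ascending limb, where 25 had an unadjusted p below 0.05 with the trend, 14 in the collecting duct, 8 for proximal tubule against thick ascending limb, 1 for thick ascending limb against collecting duct, and 1 enriched in the collecting duct. Array weights, 0.248 for each glomerulus library, gave 12 in the glomerulus, 7 in the thick ascending limb, 15, 43 and 42 for proximal tubule against glomerulus, thick ascending limb and collecting duct, 13 and 16 for glomerulus against thick ascending limb and collecting duct, 20 for thick ascending limb against collecting duct, and 1 and 7 enriched in glomerulus and collecting duct. Flow cell B alone gave 9 for proximal tubule against thick ascending limb. Flow cell D alone, with the fewest reads (737311), gave 28 among the segments, 22 in the glomerulus, 1 in the thick ascending limb, 13 in the collecting duct, 18 for proximal tubule against glomerulus, 5 for proximal tubule against thick ascending limb, 1 for thick ascending limb against collecting duct, and 1 enriched in glomerulus and 1 in collecting duct. An estimated correlation gave 0 lists in camera and fry gave 0, against 8 with the preset correlation of limma's camera; with the preset correlation 11 of the 44 tests had an unadjusted p below 0.05.

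With tubule segments only, the counts were 42 in the proximal tubule, 26 in the thick ascending limb and 35 in the collecting duct, and 39, 41 and 26 for proximal tubule against thick ascending limb, proximal tubule against collecting duct and thick ascending limb against collecting duct. There miR-182 went from 1.31 to −0.70 in the proximal tubule and from 1.12 to −0.91 in the thick ascending limb, each now against 2 segments. let-7b-5p in the glomerulus went from −1.24 to 0.18 without the glomerulus library of rat 3, and equally without rat 3; without other single libraries it reached −2.65.

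With 1 library or 1 rat left out, a lone glomerulus library being assumed to vary like the other segments, counts ranged from 27 to 85 among the segments, 9 to 62 in the proximal tubule, 23 to 72 in the glomerulus, 0 to 34 in the thick ascending limb and 9 to 38 in the collecting duct. By pair they ranged from 20 to 73, 3 to 37 and 7 to 40 for proximal tubule against glomerulus, thick ascending limb and collecting duct, from 15 to 44 and 19 to 67 for glomerulus against thick ascending limb and collecting duct, and from 0 to 26 for thick ascending limb against collecting duct. Enriched miRNAs ranged from 3 to 14 in the proximal tubule, 1 to 5 in the glomerulus, 0 to 1 in the thick ascending limb and 0 to 12 in the collecting duct, and lists from 4 to 10. The lists numbered 4 without the glomerulus library of rat 1. Leaving out rat 2 gave the lows of 27 among the segments and 9 in the collecting duct.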

Other observations

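The miRNA lists were fixed before the data were examined, and the tests of few reads in the glomerulus library of rat 3 and of reads misassigned between libraries were written before their result was seen; the other tests of explanations and hypotheses here, the splits of the libraries included, were chosen after the result had been seen.

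Lists not yet described gave few calls in limma with Benjamini-Hochberg adjustment. Of 9 miR-30 members, abundant in kidney and known from podocytes, 1 rose in the collecting duct, miR-30c-2-3p by 1.25, and 2 when adjusted over the list alone; in the glomerulus 0 passed and 1 had an unadjusted p below 0.05, with miR-30a-5p at 0.28 and miR-30d-5p at 0.38. Of 8 members of the miR-10/miR-196 Hox clusters, miR-10a-5p alone passed, lower in the glomerulus and higher in the collecting duct. Of 14 let-7/98 members, let-7g-5p rose in the proximal tubule by 1.63, let-7b-5p and let-7g-5p fell in the glomerulus by 1.24 and 1.52 (1 when adjusted over the list alone), and let-7d-3p fell in the thick ascending limb. The glomerulus call of let-7b-5p was lost, and its sign turned to 0.18, without the glomerulus library of rat 3; it held in 10 of 18 alternative settings (adjusted p up to 0.40). Of 8 miRNAs of the kidney injury list, miR-21-5p rose in the proximal tubule, and miR-210-3p, a hypoxia miRNA, fell in the glomerulus by 2.53 and rose in the collecting duct by 2.38. The collecting duct call of miR-210-3p was lost without any 1 collecting duct library, the rat 1 or rat 2 library of the proximal tubule or thick ascending limb, or the rat 3 glomerulus library (adjusted p up to 0.32), with the rat as a random effect, with flow cell D alone, or with tubule segments only (adjusted p up to 0.29).

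Among markers of other cells, 0 of 3 leukocyte members passed in any segment. At an unadjusted p below 0.05, 2 were higher in the collecting duct and 1 was lower in the thick ascending limb. Adjusted over the list alone, 2 passed as higher in the collecting duct and 1 as lower in the thick ascending limb. Of 3 endothelial members miR-221-3p rose in the collecting duct by 2.23, a call that held in 4 of 11 fits with 1 library left out (log2 from 1.21 to 3.25) and 10 of 18 alternative settings (adjusted p up to 0.25); in the thick ascending limb 0 passed, 2 had an unadjusted p below 0.05 and 1 was lower when adjusted over the list alone. miR-27a-3p rose in the collecting duct by 1.28, held in 4 of 11 fits with 1 library left out and 14 of 19 alternative settings (adjusted p up to 0.34 and 0.19). Of 9 members of the miR-17/92 clusters 0 passed, with 1 at an unadjusted p below 0.05 in the proximal tubule and 1 in the glomerulus. The measured member of the neuronal list, miR-9a-5p, rose in the collecting duct and fell in the glomerulus by 2.99, the latter lost without the rat 3 library of the proximal tubule, glomerulus or thick ascending limb (adjusted p up to 0.28; −3.83 and −2.15 without the glomerulus libraries of rats 1 and 3), and with array weights or flow cell A or D alone (adjusted p up to 0.45). The glomerulus fall of miR-9a-5p is against a mean that holds its collecting duct peak. The measured member of the striated muscle list and both of the miR-34/miR-449 family did not pass in any segment, with 0 at an unadjusted p below 0.05. The erythroid and hepatocyte lists had 0 measured members. Since camera sets a list against the other miRNAs, its direction need not be the sign of the list's median. Camera and the median log2 value of a list differed in sign, with no call, for miR-200 in the proximal tubule (lower by camera, median 0.59), for the kidney injury list in the thick ascending limb (higher by camera, median −0.13), and in the glomerulus for the miR-10/miR-196, let-7/98, kidney injury and miR-17/92 lists (higher by camera, medians −0.58, −0.47, −1.18 and −0.90).

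In the glomerulus 28 miRNAs were lower and 9 higher. Few reads in the library of rat 3 should spare abundant miRNAs, yet 65 miRNAs with a mean of at least 100 had a median of −0.62, and 49 of them were lower. The error of 0.11 counts miRNAs of the same libraries as replicates. The mean was taken over all runs, most of them tubule runs, which favours miRNAs high in the tubules. The test therefore cannot decide how far missing reads made the asymmetry. For the scaling of the deposited values the test is void: at least 44.6% of calls were higher under the 3 rescalings, but these draw the medians of the libraries together by construction, and 27, 26 and 21 of the 28 lower calls stayed lower by median of ratios, same total and quantiles, so scaling cannot be told apart from a true difference. The library of rat 3, which has the lowest summed value, goes with the asymmetry, since without it 42.3% of calls were higher, 11 against 15 lower. A true lower miRNA content of the glomerulus, the tissue difference the design names, was not tested and stays open.

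miR-192-5p stood in the glomerulus at 6.71% (rat 1) and 3.66% (rat 3) of its proximal tubule level, a level that proximal tubule RNA in the glomerulus libraries might bring: of 61 miRNAs with at least 100 in the proximal tubule of both rats, 0 stayed under 0.5 of that percent in both rats, the bound for excluding it. Such RNA needs the full percent of each, however, and reads counted afterwards go against it as the whole source: miR-182 had 415 of 870 needed reads, miR-375-3p 124 of 239, and miR-411-5p, miR-203a-3p and miR-203b-3p together 0 whole reads of 60.3. At the lowest level relative to miR-192-5p in any rat, miR-182 and miR-375-3p reached 75.9% and 72.4% of the need, and miR-411-5p, miR-203a-3p and miR-203b-3p together needed 39.8 reads, with 0%, 2.07% and 0% of the need of each seen. Of 98 miRNAs that needed at least 10 reads 3.06% were under 10% of the need, against 1.19% to 6.40% between libraries of the same tubule segment (2 joined against the remaining rat), where 1 of 9 comparisons was higher, and 4, 4 and 1 were higher with needs below 100, 60 and 40 reads; this lies inside the spread between rats, if high in it, so such RNA cannot be told apart from expression in the glomerulus itself, which was not tested. RNA of the thick ascending limb or collecting duct is argued against as the whole source. miR-182 reached at most 12.2% of the level that such RNA would then bring. This rests on 1 miRNA, and such RNA as a part of the source was not tested. For reads misassigned between libraries, the percent of miR-192-5p varied by at most 1.12 times over the flow cells. The same pool ran on all of them, so a constant rate would give this too. The bound set beforehand, 1.5 times, could not separate the cases.

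The miRNAs miR-411-5p, miR-541-5p and miR-409b, which lie in the Dlk1-Dio3 cluster, were higher in the proximal tubule; miR-409b is not in the fixed list and was joined to it after its values were seen. Neither 1 library nor scaling accounts for the fold, as the lowest log2 value was 3.13 with any 1 library left out and 3.33 over the 3 rescalings, although miR-409b lost its call without the proximal tubule library of rat 3 (adjusted p = 0.07). The 5 miRNAs of the neuronal, miR-143/miR-145 and miR-199/miR-214 lists had a median of −0.17 in the proximal tubule, from −1.70 for miR-9a-5p to 0.84 for miR-199a-3p. They cannot decide whether RNA of neuronal or mesenchymal cells is present there. Other segments carry these miRNAs too, and miR-9a-5p was higher by 4.42 in the collecting duct. A difference in the activity of the Dlk1-Dio3 cluster between segments is a hypothesis that these values leave open, found and tested on the same data.

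Neighbouring miRNA genes may share 1 segment profile, a hypothesis tested on 23 pairs of genes within 10 kb among 95 miRNAs with a mean of at least 10. The median difference of their centred segment means was 0.473 (root mean square, log2), against a median of 1.01 and a 2.5th percentile of 0.656 for shuffled genes (permutation p = 0.00032; the smallest possible was 1e-05). A first measure, the correlation over libraries, gave a permutation p = 7e-05 and was replaced because libraries cluster by segment. The closest were miR-200b-3p and miR-429 at 0.07 and let-7e-5p and miR-125a-5p at 0.19, while miR-182 and miR-96-5p differed by 1.37. The pair at the median, miR-100-5p with miR-3596a, is uncertain, since the values of miR-3596a are identical to those of let-7a-5p. Several pairs share a cluster, and the shuffled genes were not matched for abundance.

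Other splits of the 11 libraries into groups of the same sizes, made without regard to the rat, showed how many calls a regrouping gives. They mix libraries of different segments and can carry segment differences, so they are no pure chance level. The glomerulus was not among the segments split. The proximal tubule gave 24 miRNAs against at most 17 in the other splits, and 1 of 100 splits, the real one, was as high. The collecting duct gave 23 against at most 18, with 1 of 100 as high. The thick ascending limb gave 4 against up to 15 in another split, with 6 of 100 as high, so chance cannot be excluded for it. Between tubule segments the 10 splits are too few for a share under 0.05: proximal tubule against thick ascending limb gave 15 and the highest other 0 (1 split as high), proximal tubule against collecting duct 19 and 0 (1 split), and thick ascending limb against collecting duct 4 and 4 (2 splits). The highest others of 0 come from limma with Benjamini-Hochberg adjustment.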
